A study of Homo sapiens with 12 samples.

How the data were processed

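RNA sequencing of 12 libraries was analysed from a single table of FPKM values (fragments per unit of transcript length, scaled to the mapped fragments) that the authors deposited, with 60557 Ensembl genes and a column per library. Per the labels' protocols, organoids were grown in steps of embryoid body formation, neural induction and neural maturation, and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, the tools were cutadapt 3.7, HISAT2 2.2.1 and StringTie 2.2.0, and the genome build was GRCh38. Their settings, the annotation release and whether strand was counted are not given in the sources used here. FPKM divides by gene length and by the fragments mapped in each library, so a few very abundant genes in a library lower the values of all the others. The FPKM sums of the libraries differed, from 376675 to 511432, and no rescaling was applied in the main analysis.

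Reads per gene could not be recovered from the values. Among genes under 0.3 FPKM, between 2.09% and 3.81% shared a single ratio between a library and the passage 40 WT library. That ratio was taken as relative depth, which ran from 0.73 to 1.04, with a largest inconsistency of 0.041 (log2) between pairs. Absolute depth is unknown, so no counting intervals are given. Pearson correlations of log2 values between libraries of a group lay between 0.975 and 0.991, and no pair was identical.

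Groups were taken from the sample descriptions: WT hESCs (n = 2), KO hESCs (n = 3), WT organoids (n = 3) and KO organoids (n = 4). The column names give a group to the 6 CO5 organoid columns but do not match single sample titles, since the titles number repeats in another way. Their numbers 1 and 2 are those of the column names, and only an alternative added after the data were seen pairs them. Because the labels do not say whether libraries came from separate cultures, p-values measure only the spread between these samples, which may be technical. Clone 33 and clone 36 each gave 2 organoid libraries that count separately in the main test.

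Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Genes with at least 1 FPKM in as many libraries as the smaller group were tested. KO and WT were compared within each stage from the libraries of that stage alone. Organoids were compared with hESCs within each genotype, and the interaction of genotype and stage was tested, from all 12 libraries. Organoids of clone 36 and clone 33 were compared in a fit with 3 organoid groups. SPAST was also tested with an exact two-sided permutation of library labels, and overlaps with Fisher's exact test, both in R. On simulated data with known changes, false calls made up 4.07% of calls in the hESC design, 3.49% in the organoid design, 3.17% between KO stages, 5.23% for the interaction and 3.82% between clones. Of genes changed by 1 (log2), 28.1% were recovered for the interaction and 18.7% between clones. The simulated libraries were drawn independently, with no shared clone or culture, and the changed genes came from those averaging about 5 FPKM or more. These shares may therefore not hold for libraries of the same clone or culture, or for low genes.

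Named genes were chosen by a rule fixed before the data were examined: SPAST, and the 10 largest rises and 10 largest falls among passing genes with a mean of at least 5 FPKM in the higher group. For comparisons of genotypes or clones the libraries of both sides could not overlap. Symbols beginning LOC, LINC, MIR, SNOR, RNU, RNA5 or RN7S, and clone-named, unnamed, XIST, TSIX and Y-linked genes were left out, but mitochondrial tRNA genes were not. If fewer than 10 genes passed, the 5 highest and 5 lowest by unadjusted p were given as not passing. From each list past the threshold up to 4 genes with the lowest p were taken. Other genes in the text are members of the fixed lists or are said to be chosen later, and some genes that were tested and count in the totals are not reported here.

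A total of 37 gene lists for cell types, regions, pathways and complexes was also fixed beforehand. Each was counted and tested with camera in limma (preset correlation 0.01, Benjamini-Hochberg over lists), and again with an estimated correlation and with fry. Marker lists are read as levels in bulk RNA, not as shares of cells. The lists covered hereditary spastic paraplegia (HSP) genes, microtubule severing, tubulins, axonal transport, ER shaping, pluripotency, mesendoderm, neuroectoderm, forebrain, midbrain to spinal cord, radial glia, intermediate progenitors, cell cycle, excitatory and inhibitory neurons, and synapse. They also covered astrocytes, oligodendrocytes, choroid plexus, mesenchyme, muscle and cartilage, epithelium, neural crest, retina, endothelium, microglia, Notch, WNT, the unfolded protein response, hypoxia, p53, immediate-early genes, mitochondrially encoded genes, ribosomal proteins, histones, imprinted genes and the 20q11.21 region.

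Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, equal library sums (TPM), quantile normalization, a 2-fold minimum, no intensity trend and each library left out in turn. Others were all 12 libraries in the fit, organoid libraries averaged per culture or clone, culture or clone as a correlated unit (statmod 1.5.0), CO5 libraries only, each clone alone and passage 40 only. The replicate block by column number, and list tests under further settings, were added after the data were seen. In a first run the filter was recomputed for each left-out library and SPAST dropped out of some hESC fits. The genes tested are now those of the full comparison, a choice made after that run.

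Coordinates come from GENCODE release 29 on GRCh38, in which 58482 of the gene identifiers were found. Of 13 genes named MARCHF in the table, 3 have an identifier that belongs to another symbol, so these genes are not interpreted. A second sheet listing identifiers without measurements was not used here.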

Results

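RNA was sequenced from human embryonic stem cells (hESCs) of the H9 line, an established human pluripotent cell line, and from cortical organoids grown from it. SPAST encodes spastin, an enzyme that severs microtubules, and its mutation causes the hereditary spastic paraplegia SPG4. The series compares unedited (WT) material with lines in which SPAST exon 17 was knocked out (KO). Of 12 libraries, 2 were WT hESCs (passages 40 and 52), 3 were KO hESCs (clones 22, 33 and 36, all at passage 40), 3 were WT organoids and 4 were KO organoids at day 100. The KO organoids came from 2 clones, with 2 libraries each from clone 33 and clone 36. One WT organoid library carries the culture name CO3 and the other 6 organoid libraries carry the name CO5 or CO5-1. The deposited values are FPKM for 60557 genes. Library sums ran from 376675 to 511432 FPKM, and between 13181 and 16598 genes reached 1 FPKM. Total read counts are not part of the values used here, but low values gave relative depths between 0.73 and 1.04 times that of the passage 40 WT library. The spread between libraries of a group therefore sets the precision of every value below, and nothing in the labels says whether libraries of the same clone came from separate cultures.

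The first question was whether the libraries carried the edit named in their labels. SPAST (ENSG00000021574) was lower in all 7 KO libraries than in every WT library of the same stage. In hESCs it stood at 4.56 and 8.05 FPKM in the WT libraries and at 0.751, 0.528 and 0.95 FPKM in KO clones 22, 33 and 36. In organoids it was 13.2 ± 2.79 FPKM in WT (SD, n = 3) and 1.95 ± 0.48 FPKM in KO (SD, n = 4). The KO mean was 11.8% of the WT mean in hESCs and 14.7% in organoids. On the log2(FPKM + 1) scale, SPAST fell by 2.27 in organoids (SE 0.19, limma adjusted p = 0.000842). An exact two-sided permutation test gave p = 0.0286, the smallest that 35 splits allow. It treats libraries of the same clone or culture as independent. In hESCs the log2 difference was -2.03 (SE 0.28, adjusted p = 0.247), which missed the threshold. The exact permutation p was 0.1 there, the smallest that 10 splits allow. With all 12 libraries sharing an estimate of spread, the adjusted p for hESCs was 0.0128. The gene lies on chromosome 2 of GRCh38, from 32063547 to 32157637 on the plus strand. In the annotated 17-exon transcript SPAST-201, exon 17 runs from 32154374 to 32157637. It is the last exon and holds 3264 of 5277 bases (61.9%), of which 120 are coding and the rest, with the stop codon, is annotated as 3′ UTR. A value per gene does not show which exons the remaining reads came from.

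**Figure D1:**
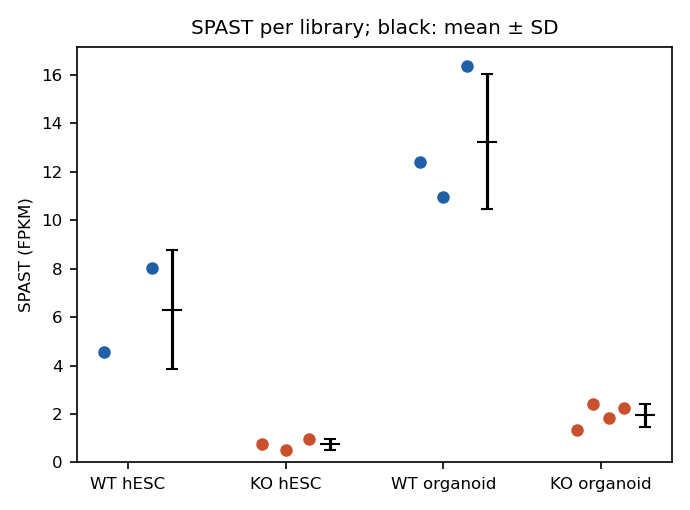
SPAST in each of the 12 libraries (points, FPKM on the vertical axis) by genotype and stage, with the mean and SD of each group in black. The KO libraries lie between 0.528 and 2.41 FPKM and the WT libraries between 4.56 and 16.4 FPKM.

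The second question was what the knockout changed in undifferentiated cells. Few genes separated the 3 KO clones from the 2 WT libraries. Only 2 of 14509 genes tested passed an adjusted p of 0.05 with limma, against 646 at an unadjusted p under 0.05. UBE2F-SCLY, a read-through transcript joining its neighbours UBE2F and SCLY, was lower in KO at 0.735 ± 0.29 FPKM (SD, n = 3) against 9.29 ± 0.407 FPKM (SD, n = 2), a log2 change of -2.58 (SE 0.23, adjusted p = 0.0452). It shares sequence with both genes, so the assignment of its reads is uncertain. SCLY itself, added after its values were seen, was listed at 9.68 and 6.27 FPKM in WT and 15.9, 18.1 and 12.9 FPKM in KO. AL049844.1, named here after its values were seen, was the other, with 0.028 and 0.0262 FPKM in WT and 5.25, 3.94 and 5.33 FPKM in KO (log2 change 2.50 (SE 0.23, adjusted p = 0.0452)).

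Below the threshold, the genes with the lowest unadjusted p that were higher in KO hESCs were INO80B (1.76 (SE 0.20, adjusted p = 0.179)), a subunit of the INO80 chromatin remodeler, and IFITM1 at 346 ± 24.9 against 167 ± 24.1 FPKM. They were followed by PPAN, NUP62 and UBE2W, with log2 differences of 1.03, 0.94 and 1.15. Those lower in KO, besides SPAST, were the collagen chaperone SERPINH1 (-0.98), the recycling-endosome GTPase RAB11A (-1.01), glutathione peroxidase GPX1 (-0.91) and the selenium carrier SELENOP (-1.73). Their adjusted p values lay between 0.655 and 0.86, apart from INO80B and SPAST. Of 36 lists tested, the camera test passed for the ribosomal proteins alone (26 genes, median log2 change -0.12, adjusted p = 0.0201). With an estimated correlation its adjusted p was 0.789, no member passed alone or when adjusted over the list alone, and RPL4 had the opposite sign (0.55). The call also ended without any 1 of the libraries except clone 33 (adjusted p = 0.121 without passage 40, 0.235 without passage 52, 0.0757 without clone 22 and 0.313 without clone 36), and the median was -0.00863 without clone 36 and -0.25 without clone 33. The WT libraries differed in passage. At passage 52 mitochondrial genes held 23.7% of the FPKM sum, against 15.1% at passage 40 and 15.6% to 19.3% in the KO clones, and that library stood apart in the pluripotency-associated gene ZFP42, at 12.8 FPKM against 78.8 FPKM at passage 40 and 81, 84.9 and 78.8 FPKM in the KO clones. Without the passage 52 library no gene passed, and without the passage 40 library 37 did. In simulated data of this design, 83.1% of genes changed by 2 on the log2 scale and 19.5% of those changed by 1 were recovered. Those data gave 123 calls against 2 here. With more calls the adjusted threshold is easier to reach, so these shares may be too high for the real hESC comparison.

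The main comparison asked how KO cortical organoids differed from WT organoids at day 100. Several genes that mark the forebrain and its excitatory neurons were far lower in KO organoids of both clones, while the list of genes shared by neurons of all kinds had a median log2 change of -0.11 and did not pass. TBR1, a transcription factor of deep-layer cortical neurons, was 62.9 ± 26.7 FPKM in WT (SD, n = 3) and 0.855 ± 0.365 FPKM in KO (SD, n = 4). Some genes of the extracellular matrix and 3 astrocyte genes were higher in KO, among them SPARCL1 at 351 ± 44.9 against 52.2 ± 23.6 FPKM, while the astrocyte gene FGFR3 was lower. The thyrotropin-releasing hormone gene TRH was 469.9 ± 99.8 FPKM in KO and 32.3 ± 20.2 FPKM in WT.

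In all, 640 of 16874 genes tested passed with limma, 321 higher and 319 lower in KO, and 533 of the 640 are protein coding. The WT and KO values of all 640 did not overlap. Over the tested genes 18.5% did not overlap. Chance gives 5.71% if the libraries are independent, and more if libraries of the same culture or clone resemble each other. In simulated data of this design with independent libraries, 91.0% of genes changed by 2 on the log2 scale and 55.9% of those changed by 1 were recovered. Treating the libraries of a culture or clone as a correlated unit left 137 genes (60 higher, 77 lower). Averaging them (2 WT against 2 KO values) called 43 (11 higher, 32 lower), 42 of them among the 640. Without the first WT CO5 library 143 passed. Mitochondrial genes held 17.52%, 18.92% and 17.04% of the FPKM sum in the WT libraries and 19.09%, 19.98%, 21.52% and 19.54% in the KO libraries, so this share also differed between the groups without overlap. TBR1, FEZF2, EMX1, SLA and NEUROG2 passed in all 3 fits (correlated unit, averaged, and without the first WT CO5 library), as did TRH, CAT, TM4SF1, MAP3K13, EGFL6 and ZNF582-AS1. NEUROD6, NEUROD2, CPNE6 and TTR, named below among the largest falls, passed in none of them, nor did SLC5A7 among the largest rises. Of the other rises, SPARCL1 and COL9A1 lost their call in the averaged fit, and GDF1 kept its call in that fit only.

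The largest falls under the naming rule were headed by TBR1 (-5.05 (SE 0.28, adjusted p = 0.000155)) on chromosome 2 from 161416094 to 161425870. FEZF2, which specifies subcortical projection neurons, fell by 4.53 (SE 0.37) and NEUROD6, a gene of postmitotic cortical neurons, by 4.53 (SE 0.78). EMX1, a dorsal telencephalic homeobox gene, was listed at 11.3, 25.5 and 19.3 FPKM in WT and 0.0602, 0, 0.0554 and 0 FPKM in KO, a log2 change of -4.19 (SE 0.24, adjusted p = 0.000155). The adaptor gene SLA (-4.00), the proneural gene NEUROG2 (-3.72), CPNE6 (-3.29) and NEUROD2 (-3.29, adjusted p = 0.0432) were also among them. TTR, which encodes transthyretin and is abundant in choroid plexus, was 2194 ± 928 FPKM in WT and 228 ± 207 FPKM in KO (-3.58 (SE 0.60, adjusted p = 0.0174)). The rule leaves out long noncoding RNAs with LINC symbols. One of these, LINC01551, named after its values were seen, had the largest fall of all called genes (-5.21 (SE 0.41, adjusted p = 0.000795)).

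The 10 largest rises under the rule began with TRH (4.00 (SE 0.40, adjusted p = 0.00206)). Catalase, CAT, was listed at 0.0732, 0 and 0 FPKM in WT and 17.9, 17.4, 11.5 and 11.8 FPKM in KO (3.91 (SE 0.19, adjusted p = 9.43e-05)). In hESCs CAT was 6.81 FPKM in the passage 40 WT library, 0.213 FPKM in the passage 52 WT library and 4.68, 6.24 and 4.71 FPKM in the KO clones. The kinase gene MAP3K13 (3.01, 17.6 ± 4.26 against 1.27 ± 0.308 FPKM) followed the same order, with 3.2 FPKM at passage 40 and 0.247 FPKM at passage 52. TM4SF1 (3.07), EGFL6 (2.98), SPARCL1 (2.83), the collagen gene COL9A1 (2.62) and the choline transporter SLC5A7 (2.51, adjusted p = 0.0197) also rose. ZNF582-AS1 (2.89) is an antisense transcript, and the sources used here do not say whether strand was counted. GDF1 (3.19) lies within the span of CERS1 on the same strand of chromosome 19, so its reads cannot be separated with certainty, and 1 KO library held 4.17 FPKM against 25.4, 27.5 and 27 FPKM in the others.

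**Figure D2:**
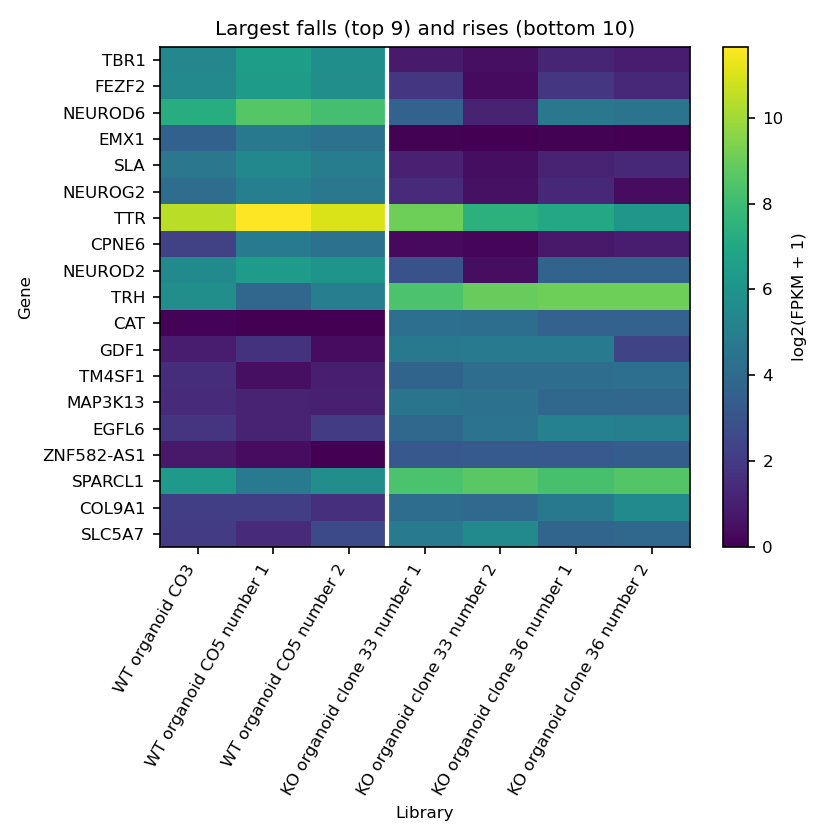
Genes with the largest falls (9 shown) and the 10 with the largest rises under the naming rule in KO organoids, as log2(FPKM + 1) in colour, with 1 column per organoid library. WT libraries are left of the white line. EMX1 lies between 11.3 and 25.5 FPKM in WT and at 0.0602 FPKM or below in KO.

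Of the 36 lists tested between KO and WT organoids, 12 passed the camera test with a preset correlation of 0.01, 7 lower and 5 higher in KO. None of the 12 held with an estimated correlation, for which the lowest adjusted p was 0.439. With fry, which tests whether the genes of a list move on balance to a side, 3 passed: cortical excitatory neurons (adjusted p = 0.00542), forebrain regional identity (0.0287) and mesenchyme (0.0287). For several lists the medians against WT differed between clone 33 and clone 36. They were, in that order, -0.74 and -0.25 for radial glia, -0.65 and -0.25 for choroid plexus, -0.44 and -0.16 for the Notch pathway, -0.58 and -0.0672 for ribosomal proteins, 0.55 and 1.28 for midbrain, hindbrain and spinal identity and 0.29 and 0.80 for WNT targets. The camera call ended in clone 36 alone for choroid plexus (adjusted p = 0.0694), the Notch pathway (0.0778) and ribosomal proteins (0.604), and in clone 33 alone for WNT targets (0.136).

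Of 24 cortical excitatory neuron genes, 13 fell, 1 rose and 10 did not pass (adjusted over the list alone, 15 fell and 2 rose), with a median log2 change of -1.41 (camera adjusted p = 1.83e-09, adjusted p = 0.439 with an estimated correlation). BCL11B, a gene of corticospinal neurons, fell by 3.12 (SE 0.21) from 13.7 ± 3.66 to 0.665 ± 0.247 FPKM, and CRYM fell by 2.08 (SE 0.16). The vesicular glutamate transporters moved apart: SLC17A7 fell from 65.7 ± 29 to 8.23 ± 0.971 FPKM, and SLC17A6, which is more common in subcortical neurons, rose from 20 ± 6.72 to 40.1 ± 3.1 FPKM (log2 change 1.01, adjusted p = 0.0333). Of 15 forebrain identity genes, which share TBR1 and FEZF2 with that list, 7 fell and 8 did not pass (adjusted over the list alone, 9 fell and 1 rose), with a median of -1.25 (camera adjusted p = 1.11e-07, adjusted p = 0.439 with an estimated correlation). The falls included LHX2 (-3.16 (SE 0.28, adjusted p = 0.000963)), DMRTA2 and SIX3.

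Of 22 radial glia genes, which mark neural stem cells of the cortex, 7 fell and 15 did not pass (adjusted over the list alone, 9 fell and 1 rose). Their median was -0.59 (camera adjusted p = 0.000242, adjusted p = 0.439 with an estimated correlation). PTPRZ1 fell by 1.39, from 60.1 ± 15.2 to 22.1 ± 4.78 FPKM, MOXD1 fell by 1.27, and HOPX, a gene of outer radial glia, fell by 0.96. The cell cycle list had medians against WT of -1.24 in clone 33 (23 genes fell) and -0.50 in clone 36 (0 fell). Over all KO libraries it had a median of -0.88 over 30 genes (camera adjusted p = 5.76e-14, adjusted p = 0.439 with an estimated correlation). Of these, 3 fell over all genes tested, RRM2 (-1.25), BUB1B (-0.93) and MCM4 (-0.72), and 25 fell when adjusted over the list alone. Of 17 Notch pathway genes, DLL1 (-0.85) and HES5 (-1.22) fell and 15 did not pass, HES1 among them with the opposite sign (0.82, adjusted p = 0.0614). Adjusted over the list alone, 5 fell and 1 rose (median -0.32, camera adjusted p = 0.00903, adjusted p = 0.448 with an estimated correlation). The median was -0.21 without the second clone 33 library and -0.19 without the WT CO3 library, where the call ended (adjusted p = 0.207).

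Of 17 choroid plexus and ependyma genes, 3 fell and 14 did not pass (adjusted over the list alone, 4 fell). The 3 were TTR, the serotonin receptor HTR2C (-2.22) and CLIC6 (-1.35), and the list's median was -0.40 (camera adjusted p = 0.000773, adjusted p = 0.448 with an estimated correlation). The median was -0.68 without the WT CO3 library, -0.26 without the first WT CO5 library and -0.66 without the first clone 36 library. Ribosomal protein genes had a median of -0.32 over 26 genes (camera adjusted p = 0.00868, adjusted p = 0.744 with an estimated correlation), and no member passed, alone or adjusted over the list alone. The call ended without the first WT CO5 library (-0.23, adjusted p = 0.108), the second (-0.14, adjusted p = 0.478) or the second clone 33 library (-0.16, adjusted p = 0.146), and the median was -0.60 without the WT CO3 library.

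Of 17 mesenchyme and matrix genes, 7 rose and 10 did not pass (adjusted over the list alone, 9 rose), with a median of 0.56 (camera adjusted p = 1.05e-06, adjusted p = 0.439 with an estimated correlation). The fibrillar collagens COL1A2 (from 8.22 ± 0.75 to 28.5 ± 3.33 FPKM), COL3A1 (2.29) and COL1A1 (1.71) rose, as did ACTA2 (1.19). Of 17 astrocyte genes, SPARCL1, APOE (1.46) and CLU (0.92) rose, FGFR3 (-1.64) fell and 13 did not pass. Adjusted over the list alone, 7 rose and 2 fell (median 0.54, camera adjusted p = 0.00884, adjusted p = 0.467 with an estimated correlation). The median was 0.33 without the first WT CO5 library and 0.32 without the second, where the call ended (adjusted p = 0.0812). GFAP, the classical astrocyte filament gene, was 16.3 FPKM in the WT CO3 library and between 1.53 and 2.95 FPKM in the other 6.

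Lists of other regions lay higher in KO with few single genes past the threshold. The neural crest and peripheral neuron list had a median of 1.03 over 10 genes (camera adjusted p = 0.000242, adjusted p = 0.439 with an estimated correlation). Its median against WT was 1.79 in clone 33 and 0.46 in clone 36. The intermediate filament gene PRPH rose (2.50 (SE 0.35, adjusted p = 0.00774)), and 2 rose when adjusted over the list alone. TH (2.13, adjusted p = 0.0833) and RET (1.15) did not pass. The midbrain, hindbrain and spinal list had a median of 0.97 over 11 genes (camera adjusted p = 0.00473, adjusted p = 0.451 with an estimated correlation). PAX8 rose (1.82), GBX2 fell (-0.98) and 9 did not pass, PAX5 (1.08) and EN1 (1.37, 18.6 ± 6.39 against 7.45 ± 4.92 FPKM) among them, while 7 rose and 1 fell when adjusted over the list alone. HOX genes of the hindbrain and spinal cord reached 1 FPKM in the WT CO3 library alone, where 20 did. Without the filter on low values this list had a median of -0.23 and did not pass. Of 15 WNT pathway targets, WIF1 rose (1.48), LEF1 fell (-1.27) and 13 did not pass, with BMP4 at 0.92 and RSPO3 at 1.10. Adjusted over the list alone, 5 rose and 1 fell (median 0.68, camera adjusted p = 0.00288, adjusted p = 0.448 with an estimated correlation).

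**Figure D3:**
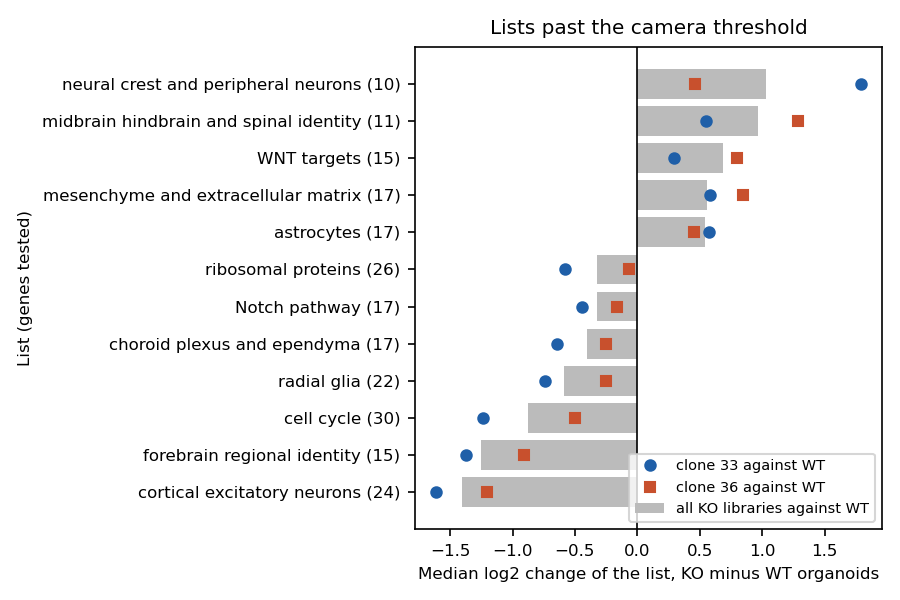
Median log2 change (KO minus WT organoids, horizontal axis) of the 12 lists past the camera threshold, with the number of genes tested in brackets. Bars take all KO libraries together, circles clone 33 and squares clone 36, each against the same 3 WT libraries. Cortical excitatory neuron genes have medians of -1.61 in clone 33 and -1.21 in clone 36.

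The other 24 lists did not pass in organoids. Synapse and pan-neuronal genes had a median of -0.11 over 30 genes (camera adjusted p = 0.913), with SYT4 past the threshold (1.09) and 29 genes not. SNAP25 was 95.9 ± 22.8 FPKM in KO and 92.4 ± 8.66 FPKM in WT. Of the 23 microtubule severing and ESCRT-III genes, the class to which SPAST belongs, SPAST alone passed (camera adjusted p = 0.475). The katanin gene KATNA1 (-0.09) and the fidgetin genes FIGN (0.08) and FIGNL1 (-0.20) had small differences. No gene of the 37 tubulins and microtubule-associated proteins (0.206) or the 25 axonal transport motors (0.711) passed. Among 44 genes of hereditary spastic paraplegia, SPAST included, NIPA1 (1.64) and BSCL2 (0.80) rose (list adjusted p = 0.475). In the ER shaping and lipid droplet list (0.0885), BSCL2 and REEP5 (0.80) rose.

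Camera adjusted p values of the remaining lists were 0.0946 for inhibitory neurons, 0.206 for intermediate progenitors, 0.153 for neuroectoderm and 0.0948 for retina. They were 0.0948 for histones, 0.123 for the unfolded protein response, 0.206 for microglia, 0.21 for the oligodendrocyte lineage and 0.21 for mitochondrially encoded genes. They were 0.42 for muscle and cartilage, 0.475 for pluripotency, 0.64 for p53 targets, 0.64 for imprinted genes and 0.711 for immediate-early genes. The last were 0.719 for the 20q11.21 region, 0.76 for epithelium, 0.902 for mesendoderm and 0.912 for hypoxia. The endothelium list had too few expressed genes for a test in organoids.

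The 2 KO clones were compared because each gives its own organoids. Several genes were present in organoids of one clone and listed at or near 0 in those of the other. BEX5 (chromosome X, 102153708 to 102156057) was 81.4 and 87.5 FPKM in the clone 33 libraries and 0.0652 and 0.0612 FPKM in the clone 36 libraries, and the neighbouring TCEAL2 was 54.2 and 53.9 against 0.0966 and 0 FPKM. The retinol ester hydrolase gene PNPLA4 went the other way, at 0 in both clone 33 libraries and 15 and 13.7 FPKM in clone 36. WT organoids lay nearer clone 33 for BEX5 (30.3, 25.4 and 65 FPKM), TCEAL2 (33.7, 68.8 and 76.7 FPKM) and PNPLA4 (0 in all). For S100A6 they lay nearer clone 36, at 44.2, 35 and 60.2 FPKM, against 2.64 and 3.4 FPKM in clone 33 and 51.7 and 55.8 FPKM in clone 36. Limma called 96 of 17664 genes, 49 higher and 47 lower in clone 36, from 2 libraries each. Without any 1 of the 4 KO libraries between 12 and 25 passed, without the WT CO3 library, which enters only the estimate of spread, 243 did, and without the first WT CO5 library 55 did. SPAST did not differ past the threshold (log2 difference 0.11 (SE 0.26, adjusted p = 0.935)).

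Higher in clone 36 were PNPLA4 (3.94 (SE 0.18, adjusted p = 0.000543)), CEBPZOS (3.82), the calcium-binding protein gene S100A6 (3.77), TUSC1 (2.69), VAMP5 (2.65) and the zinc finger gene ZNF471 (2.87). The read-through transcript TMEM189-UBE2V1 (3.78), the antisense transcript ZNF528-AS1 (2.54) and the pseudogenes FAR2P2 (3.45) and FAR2P3 (2.45) were among the 10 as well, and their reads can belong to related or overlapping genes. Lower in clone 36 were BEX5 (-6.33 (SE 0.39, adjusted p = 0.000965)), TCEAL2 (-5.72), MAGEE1 (-3.86), the quinone reductase CRYZ (-3.41), PHACTR3 (-3.34) and the glutamate receptor subunit GRIN3A (-3.13). The neuropeptide genes CARTPT (-5.30) and PENK (-3.38), the CRH-binding protein CRHBP (-2.50) and PCDHGA11 (-4.10), which shares exons with its cluster, were lower too. The call of CARTPT had an adjusted p of 0.0423 and its levels were 91.2 and 95.1 against 0.29 and 3.41 FPKM.

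By list, 16 of 36 passed the camera test between the clones, and none held with an estimated correlation (lowest adjusted p = 0.204). Cell cycle genes lay higher in clone 36 (median 0.76, camera adjusted p = 9.97e-14, adjusted p = 0.445 with an estimated correlation), with TOP2A past the threshold (1.35) and 20 of 30 past it when adjusted over the list alone. Synapse and pan-neuronal genes lay lower (-0.36, camera adjusted p = 1.27e-09, adjusted p = 0.204 with an estimated correlation), with ELAVL4 (-2.16) past it and 8 of 30 adjusted over the list alone. Neural crest and peripheral neuron genes were lower in clone 36 (-1.26, camera adjusted p = 7.94e-05, adjusted p = 0.445 with an estimated correlation), with POU4F1 past the threshold (-2.33). Of 17 imprinted genes the paternally expressed NNAT fell (-2.36 (SE 0.19, adjusted p = 0.00301), list camera adjusted p = 0.000424, adjusted p = 0.231 with an estimated correlation).

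**Figure D4:**
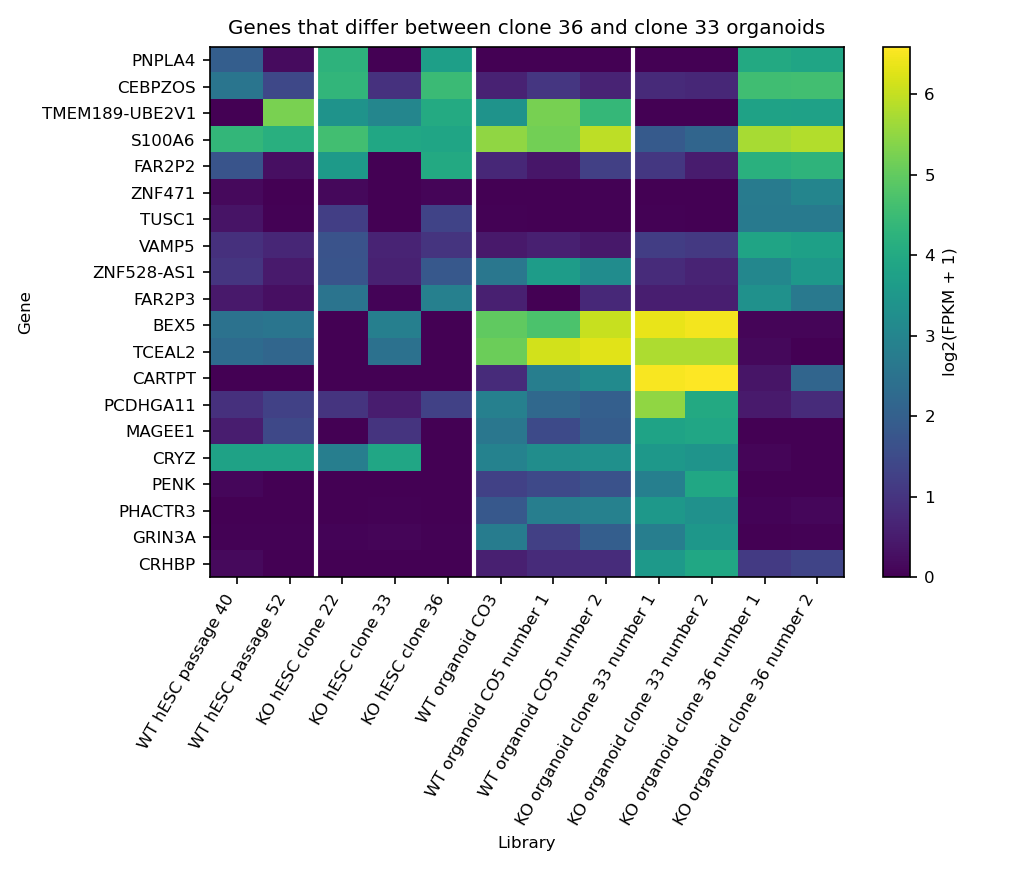
The 10 genes with the largest rises and the 10 with the largest falls under the naming rule between clone 36 and clone 33 organoids, as log2(FPKM + 1) in colour, in all 12 libraries. White lines part WT hESCs, KO hESCs, WT organoids and KO organoids. BEX5 is listed at 0 FPKM in hESC clones 22 and 36 and at 6.16 FPKM in clone 33.

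The remaining question was how cells changed from stem cells to organoids in each genotype. Pluripotency genes were lost and neuronal genes gained in both. POU5F1 fell from 772 ± 66.7 to 0.167 ± 0.148 FPKM in WT (SD, n = 2 and 3) and from 675 ± 136 to 0.0657 ± 0.0289 FPKM in KO (SD, n = 3 and 4). STMN2, a marker of neurons, rose from 2.42 ± 1.84 to 531 ± 296 FPKM in WT and from 4.25 ± 2.14 to 1217 ± 312 FPKM in KO. In WT, 12175 of 18845 genes passed, 8206 higher and 3969 lower in organoids, and in KO 13114 passed, 8234 higher and 4880 lower. The median log2 change over all genes was 0.42 in WT and 0.33 in KO. It was 0.71 and 0.53 with libraries scaled to equal sums, and 0.01 in both after quantile normalization. The share of higher genes, 67.4% in WT and 62.8% in KO, was 74.5% and 68.4% with equal sums, and 49.2% and 49.9% after quantile normalization, which gives all libraries a single distribution and so a near-even split by construction.

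In WT the largest falls under the naming rule were POU5F1 (-9.38 (SE 0.19, adjusted p = 5.14e-12)), LIN28A (-8.75), ESRG (-7.61), TDGF1 (-7.33), L1TD1 (-7.03), DPPA4 (-6.80), DNMT3B (-6.35), CYP2S1, ZSCAN10 and CNMD. The largest rises were TTR (10.50 (SE 0.62, adjusted p = 4.20e-08)), NEUROD6 (7.82), NSG2 (7.62), GPM6A (7.35), STMN2 (7.23), RTN1 (6.85), STMN4 (6.84) and SCG2 (6.47), besides the septin pseudogenes SEPT7P5 and SEPT7P8. In KO, POU5F1 (-9.29), LIN28A (-8.53), ESRG (-7.85) and DPPA4 (-6.84) again led the falls and ZFP42 joined them (-6.28). TRH (8.72), SCG2 (8.24), SPARCL1 (8.13), NSG2 (7.99), STMN2 (7.90), TTR (7.31), LY6H (7.02) and GPM6A (6.95) led the rises, with the mitochondrial tRNA gene MT-TC (7.99), whose values were uneven within hESCs, at 0.476, 726 and 0.363 FPKM in the KO clones.

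The naming rule also took entries whose values are doubtful between stages. SEPTIN2 was listed at 0 in all 7 organoid libraries and between 58.2 and 73.2 FPKM in hESCs, and the pseudogene row SEPT7P5 at 0 in all 5 hESC libraries and between 233 and 330.3 FPKM in organoids. SEPTIN3 and SEPTIN11 were likewise listed at 0 in every organoid library. Entries of the septin family are therefore not read as changes between stages, and an exact 0 in these values need not mean absence.

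All 24 pluripotency genes fell in both genotypes (medians -4.69 in WT and -4.55 in KO), and this list and the epithelium list held with an estimated correlation (adjusted p = 0.000135 and 0.00512 in WT, 0.000282 and 0.0103 in KO). Of 12 epithelium genes, 11 fell and 1 rose in each genotype, CDH1 and ESRP1 among the falls. The other lists that passed the camera test, 13 in WT and 8 in KO, did not hold with an estimated correlation. Of 30 cell cycle genes 28 fell in WT and 29 in KO (estimated-correlation adjusted p = 0.319 and 0.386), and of 30 synapse and pan-neuronal genes 28 and 26 rose (0.288 and 0.386). Cortical excitatory neuron genes rose in 20 of 24 in WT (median 3.85) and in 18 of 24 in KO (median 1.60). Forebrain identity genes passed in WT (12 of 15 rose, median 2.97, camera adjusted p = 0.00244, adjusted p = 0.558 with an estimated correlation). In KO the midbrain, hindbrain and spinal list passed (10 of 11 rose, median 2.52, camera adjusted p = 0.0181, adjusted p = 0.641 with an estimated correlation), with EN2 (3.84), EN1 (4.18) and LMX1B (2.60). Mitochondrially encoded genes had a median of -0.55 in WT, of 0.09 after quantile normalization, of -0.0869 without the passage 52 library (adjusted p = 0.413), of -0.78 without the passage 40 library and of -0.34 without the second WT CO5 library. Whether these changes differ between genotypes was tested by the interaction. Endothelium genes, 3 tested, had a median of -0.74 in WT and did not pass.

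The interaction of genotype and stage asked which genes responded to the knockout differently in organoids than in hESCs. Forebrain genes of the organoid comparison were prominent in it: TBR1 (-4.92 (SE 0.38, adjusted p = 0.000137)), FEZF2 (-4.85) and EMX1 (-4.52). The same organoid libraries enter both tests, and these values lie near those given above for organoids alone. A gene hardly expressed in hESCs has little room to differ there, so its call here is not a separate finding. In total 139 of 18845 genes passed with limma, 45 higher and 94 lower, and 2572 had an unadjusted p under 0.05. The share of higher genes was 32.4%, 29.4% with libraries scaled to equal sums and 42.6% after quantile normalization. Leaving out the passage 40 WT hESC library gave 486 genes and leaving out the passage 52 library 42. SPAST itself did not differ between stages past the threshold (log2 difference -0.24 (SE 0.33, adjusted p = 0.797)).

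No gene was called in the same direction in both stages, but hESCs had only 1 called gene per direction (0.0138 shared by chance for higher and 0.0146 for lower genes). That count therefore says little on whether the stages respond alike. At an unadjusted p of 0.01, 3 genes were higher in both (1.92 by chance, Fisher's exact p = 0.442) and 2 lower in both (0.844 by chance, p = 0.206), over 13243 genes tested in both. The 2 lower genes were SPAST and C9orf64, and the 3 higher were VGF, C5orf38 and HACD1, all named after their values were seen. Across genes, the log2 changes of the stages had a Pearson r of 0.00358 and a Spearman rho of -0.0390, which describe the genes and are no test, since genes are not independent replicates.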

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

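The tests weighed for the lower forebrain genes were written after the result was seen, except the one on scaling, and so was the count of splits for the organoid comparison.

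A test of the interaction found 139 genes whose KO minus WT difference in organoids was not that in hESCs. It uses the same organoid libraries, so for genes hardly expressed in hESCs it largely repeats the organoid comparison. TRH (3.96), SPARCL1 (2.87), EGFL6 (2.65), COL9A1 (2.64), COL23A1 (2.63), TM4SF1 (2.61), MAP1LC3C (2.50), COL3A1 (2.48), SELENOP (2.36) and NIPA1 (2.35) had the largest positive log2 differences. TBR1 (-4.92), FEZF2 (-4.85), EMX1 (-4.52), SLA (-4.32), NEUROG2 (-3.67), ST18 (-3.26), SLC17A7 (-3.22), BHLHE22 (-3.16) and BCL11B (-3.16) were among the largest negative ones. By list, 11 passed the camera test for the interaction, and none held with an estimated correlation (lowest adjusted p = 0.277). Median differences were -1.34 for cortical excitatory neurons, -1.06 for forebrain identity, -0.86 for the cell cycle, -0.78 for histones, -0.67 for choroid plexus and -0.66 for radial glia. They were 1.19 for midbrain, hindbrain and spinal identity, 0.94 for neural crest, 0.53 for WNT targets, 0.48 for mesenchyme and 0.23 for mitochondrially encoded genes, where quantile normalization gave -0.14. Leaving out a library ended the camera call in at least 1 case for choroid plexus (without passage 40, adjusted p = 0.108), mesenchyme (without passage 40, 0.0634), WNT targets (without the second WT CO5 library, 0.227), mitochondrially encoded genes (without passage 52, 0.951) and histones (without clone 22, 0.223).

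The forebrain pattern covers 37 genes of the forebrain and cortical excitatory neuron lists, of which 18 fell and 1 rose in KO organoids, with a median log2 change of -1.25. Fewer were called lower in other fits: 10 with libraries averaged per culture or clone, 11 with that unit correlated and 12 without the first WT CO5 library. Against the scaling of the libraries, the median was -1.28 after quantile normalization, with the same 18 genes called lower. Against a loss of neurons of every kind, the lower quartile of the synapse and pan-neuronal list was -0.37, well above the median of these genes. That quartile pools the clones, and the synapse list lay lower in clone 36 than in clone 33. The medians of the 37 genes against WT were -1.38 in clone 33 and -0.91 in clone 36, and a loss of neurons was not tested in each clone alone. Also open is a difference between cultures or clones unrelated to genotype, since no clone holds both genotypes. The CO5 columns hold both, with a median of -1.26 for KO against the WT CO5 libraries, but the sample titles give CO5 for WT and CO5-1 for KO, and the labels do not say whether these are 1 culture. The WT CO3 library differed from the WT CO5 libraries by a median of -0.26, and the 4 KO libraries from the WT mean by -1.15, -1.77, -0.86 and -0.92. A change of regional identity linked to the knockout may account for the pattern and was not separated from differences between lines by any test here.

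Other groupings of the same libraries were also fitted. Of 35 splits of the 7 organoid libraries into 4 and 3, the real one called 640 genes and the highest of the others 4. Those others mix WT and KO libraries, which widens their spread, so their counts do not show what chance would call. The real split ranked first of 35, the most this count can show even with independent libraries. The libraries come from 2 WT cultures and 2 KO clones, too few for such a count of splits, so chance between cultures or clones is not excluded. Fits with the culture or clone as the unit called 137 (correlated) and 43 (averaged). For KO organoids against KO hESCs the real split called 13114 genes and the highest of the other 34 called 7431. The same limits hold there. Clones 33 and 36 lie on both sides, and neither the splits nor the fit accounts for that.

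Among 65 sets of the 4 KO organoid libraries, 4 had a library standing apart by a gap above Dixon's critical value, and chance gives about 1 in 20. TRH was 323 FPKM in clone 33 number 1 and between 491 and 535 FPKM in the others (0.833). GDF1 was 4.17 FPKM in clone 36 number 2 and between 25.4 and 27.5 FPKM in the others (0.955). GBX2 was 0.874 FPKM in clone 33 number 1 and between 0.326 and 0.376 FPKM in the others (0.892). In clone 36 number 2, 16598 genes reached 1 FPKM, against 16180 to 16215 in the others (0.916).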

How the results depend on the processing

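The block by column number, and list tests under settings other than scaling, an estimated correlation, fry, averaging and leaving out CO3, were chosen after the data were seen. No call changed sign for a gene chosen for naming in the KO and WT comparisons (15 genes in hESCs, 60 in organoids), while 29 of the 60 lost their call under at least 1 setting.

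For hESCs the count of genes was 0 with a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, TPM and passage 40 only, and SPAST (-2.03) passed with all 12 libraries (adjusted p = 0.0128). The organoid count was 416 with a 2-fold minimum, 217 with no filter (83 higher, 134 lower), 324 with a mean of at least 5 FPKM, 1084 with all 12 libraries, 43 averaged (11 higher, 32 lower) and 137 with a correlated unit. The WT and KO stage counts were 7926 and 7887 with a 2-fold minimum, and 6601 and 7223 with a mean of at least 5 FPKM. The interaction count was 82 with no filter and 64 with that mean, and the clone count 43 with it. The overlap of stages was 5 genes at an unadjusted p of 0.01. Lists passing with an estimated correlation numbered 0 in hESCs, organoids, the interaction and clones, and 2 in each stage comparison. With fry they numbered 0, 3, 2 and 2, and 28 and 30. The hESC list (ribosomal proteins) was also lost with no filter, quantile normalization and all 12 libraries (0), with passage 40 only (adjusted p = 0.235) and in 4 of 5 fits without a library.

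Reversed values were few. After quantile normalization the ribosomal list in hESCs had a median of 0.0104, the mitochondrial list 0.0891 between WT stages and -0.14 in the interaction, and MT-ND3 -0.0897. With no filter the midbrain to spinal list in organoids was -0.23. The SPAST interaction was 0.19 with a pseudocount of 0.1. The cause was not tested for these changes beyond the smaller number of genes or libraries that some settings leave.

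Leaving out a library gave 0 to 37 genes in hESCs, 143 to 627 in organoids, 10080 to 12194 and 12046 to 13505 between stages, 42 to 486 for the interaction and 12 to 243 between clones. A side left with 1 library is assumed to vary like the rest. SPAST lay between -2.38 (without passage 40, adjusted p = 0.0456) and -1.68 in hESCs. Lists passing, not always the same ones, numbered 1 to 3 in hESCs and 7 to 13 for the interaction. Signs reversed for the SPAST interaction (-0.59 to 0.11, the latter without passage 40), MT-ND3 (-0.0899 to 0.79), MT-CYB (-0.0231 to 0.66) and the mitochondrial list (-0.0492 to 0.52), these without passage 52, and SPAST between clones (-0.17 without clone 33 number 1, to 0.38).

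The replicate block by column number in CO5 organoids gave 409 genes. The numbers do not pair the samples: deviations of same-numbered libraries had correlations across genes of -0.0848, -0.0360 and -0.00980. Unknown absolute depth limits what can be said of genes near 0 FPKM.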

Other observations

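The tests on clones, on the X chromosome and on the need for the knockout were chosen after the result was seen, and so were 2 of the 3 on depth. The third was written before its value was seen but after the other 2. The share tested for passage had not been seen when its test was chosen, but the values of CAT and MAP3K13 had prompted it.

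HOX genes, which mark hindbrain and spinal cord, set one WT organoid library apart. In the WT CO3 library 20 HOX genes reached 1 FPKM with a sum of 66.7 FPKM, and in each other library the sum was 0.481 FPKM or less. GFAP was 16.3 FPKM in the same library and 2.62 and 2.95 FPKM in the other WT organoid libraries.

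Between stages, 13 genes were listed at 0 in all 7 organoid libraries and at 10 FPKM or more in all 5 hESC libraries, and 3 of them are septins. The 4 genes with the opposite pattern are all septin pseudogenes.

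Genes that differ between organoids of clones 36 and 33 were compared with the stem cell clones they came from. Of 67 called genes expressed there, 56 (83.6%) differed in the same direction between hESC clones 36 and 33, against 51.0% of genes not called (Fisher's exact p = 4.53e-08), and all 25 that differed at least 2-fold in hESCs did. Of 95 called genes with a position, 17 (17.9%) are X-linked, against 3.52% of the others (Fisher's exact p = 4.34e-08), with 5 higher and 12 lower in clone 36. Over all 631 X-linked genes tested the median log2 difference was 0.01. Both Fisher tests count genes as independent although a single clone stands on each side, so their p-values describe these clones only. Sequencing depth was weighed by 3 tests. Clone 36 was the deeper clone (mean relative depth 0.96 against 0.855), and 51.0% of called genes (49) were higher there. The other 47 were lower in clone 36. That split decides nothing on depth, because FPKM is already scaled to the mapped fragments of each library. The other tests do not decide either. The smallest absolute log2 change of called genes (1.11, against 0.24 for the largest ratio of depths) is set by their selection. The median difference of 75 called genes between the WT CO5 libraries (0.13, depths 0.94 and 0.73) is kept small because these libraries enter the spread by which genes were called. A clonal state carried from stem cells into organoids, for some genes on the X chromosome, may account for part of the difference, and organoids of clone 22 were not analysed here.

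Some genes higher in KO organoids followed the passage of the WT stem cells, being high at passage 40 and near 0 at passage 52, as CAT was (6.81 and 0.213 FPKM). A WT line state at later passage would give more matching signs among the organoid calls. Over all calls together no such excess was seen: 48.5% of 367 called genes had the matching sign, against 47.7% of genes not called (Fisher's exact p = 0.791). This does not decide the question, because the labels give no passage for the organoids and a single library stands for each passage. The directions differed, with 67.2% against 59.0% for higher genes (Fisher's exact p = 0.0309) and 30.5% against 37.8% for lower genes (Fisher's exact p = 0.0464). Of called genes that differ at least 2-fold between passages, 30 of 34 higher genes and 2 of 17 lower genes had the matching sign, so most lay higher at passage 40 whichever way KO moved. For the 30 higher genes, the passage 40 WT library lay a median of 0.30 (log2) above the KO hESCs. That last test was first set aside after its value was seen, and it decides nothing on whether the knockout is needed, because the genes were picked for high values at passage 40.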
